A study of Mus musculus with 2 samples.

How the data were processed

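Splenic NK cells positive for CD27 and CD11b were flow sorted by the study from 2 mice per genotype and pooled, and 1 droplet library of 3' tags was made for each genotype, per the labels with a Single Cell 3' v2 kit. The deposited matrices hold raw counts: each value is a number of UMIs for a gene and a barcode, with no normalization, and every deposited barcode holds at least 500 UMIs. The labels name STAR, Cell Ranger 3.0.0 and Seurat and the genome build GRCm39, and the file headers name version 3.0.0. Reads were not used here. The files list 31053 gene IDs, of which 30934 were matched by ID to the GENCODE annotation of the GRCm38 build, used for positions and exon lengths alone.

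Groups were taken from the genotype labels, floxed control and NK knockout, with 1 library per group. With 1 library per group no test, p-value or spread between animals can be had, and cells are not replicates. Depth was 69853026 UMIs over 11785 control barcodes and 42795121 over 10615 knockout barcodes, a ratio of 1.63. Counts carry exact Poisson intervals, shares exact binomial (Clopper-Pearson) intervals, and ratios the exact conditional binomial interval of a pair of Poisson counts, all at 95% and for counting error only. A count of 0 is read against a floor of 3 counts over the group. List medians carry an interval from 1000 Poisson draws.

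Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which left out 857 control and 592 knockout barcodes. Scrublet in scanpy 1.11.5, at an expected doublet rate of 0.06 per library, marked 1 of the remaining barcodes (0.00477%). A caller that marks under 0.5% of over 5000 cells is taken not to have worked, so no barcode was removed as a doublet. The libraries shared 33 barcode sequences. Counts were scaled to 10000 per cell and logged, and 2000 variable genes without mitochondrial, ribosomal protein, antigen receptor and sex-specific genes gave 30 principal components. Leiden clustering at resolution 0.5 on shared neighbours among 15 nearest neighbours used leidenalg 0.10.2 and igraph 0.11.9, with anndata 0.12.19, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 under Python 3.11.15.

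Clusters were named from markers fixed before the data were examined, using the 10 genes of highest fold, detected in at least 25% of the cluster's cells, within the library that held most of the cluster. A name needed at least 3 detected markers. NK-like clusters also needed a UMI of Ncr1, Klrb1c or Klrk1 in at least 90% of cells. That share, and the exclusion of clusters led by interferon or division genes from the NK-like class, were set after the data were seen. Before the exclusion, the division cluster had been counted as NK-like.

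UMIs of NK-like cells were summed per library and divided by their total, and genes with a mean of at least 10 counts per 1000000 UMIs (CPM) over both libraries were called measured. A log2 ratio of at least 0.32 in size marked a gene as higher or lower, as a description and not a test. For 30 gene lists fixed beforehand, the median log2 ratio and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, are given as a description of these libraries. The rule for named genes, written before the data were examined, took genes of at least 50 CPM without mitochondrial, ribosomal protein, predicted, antigen receptor, haemoglobin and sex-specific genes. It named the 13 highest and 13 lowest log2 ratios whose direction held in thinned cells and under median-of-ratios scaling, up to 4 members of each list with the largest ratio, Ptger3, Ncr1, 5 integrin genes and 4 effector genes. Shares of cells with a UMI were compared after each cell was thinned to 2000 UMIs, which left out 98 control and 176 knockout NK-like cells. Ratios were also taken within clusters of at least 200 cells per library. No NK-like cluster of the main clustering held that many of both libraries, so clusters found after centring each gene within its library served for this.

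The steps were tested on simulated data. Poisson counts were drawn at the mean level and library sizes of the 7331 measured genes with 200 genes changed. For knockout over control in NK-like cells, all 100 genes changed 1.5-fold and all 100 changed 2-fold passed a log2 ratio of 0.32 in the right direction. This is the size that marks a gene, and 0% of 7131 unchanged genes passed it. Of the intervals of unchanged genes, 94.9% held the true value. Of 100 lists of unchanged genes 4 lay outside the middle 95% of random lists. Such counts hold no variation between animals or preparations.

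Other cell types were used to look at differences that reach beyond NK cells. Macrophage-like, dendritic-like and T cell-like clusters with an NK receptor in under 90% of cells were reduced to cells with at most 1 UMI over 8 NK markers. This left 97 control and 252 knockout cells with 188866 and 554026 UMIs, and 6 NK markers kept apart for the purpose stood at 4.47% and 2.05% of their NK-like level. This selection was made after 2 others on 14 markers had been seen. Exon length is the union of a gene's exons, and a gene's length-adjusted ratio is its log2 ratio minus the median of the 300 genes nearest in length. That number was lowered by 1 after the result was seen.

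Alternatives fixed before the data were examined were median-of-ratios scaling, a total without mitochondrial and ribosomal protein genes, a stricter filter (1000 genes, 5% mitochondrial UMIs), all barcodes, equal weight per cell, thinned cells, a mean over centred clusters, cells without other lineages' marker UMIs, list minima of 50 and 1 CPM, Leiden resolutions of 1 and 0.3, centring or thinning before clustering, and other settings for shares of cells. Added after seeing the data were the interferon and division clusters joined to or left out of the class used, removal of the 6% of cells with the highest doublet scores, and a proliferation list without Hmgb2, Stmn1 and Tubb5.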

Results

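Single-cell RNA profiles were measured in natural killer (NK) cells of C57BL/6 mice in which Ptger3, the gene of the E-prostanoid 3 receptor (EP3) for prostaglandin E2, was floxed. Cre driven from Ncr1, the gene of the NK receptor NKp46, deletes the gene in NK cells of the knockout group, and floxed animals without Cre served as the control. The cells were splenic and sorted by the study as positive for CD27 and CD11b. Each group is a pool of 2 mice in 1 library, so there are no replicates: no test is given, no value carries a spread between animals, and every interval is a 95% interval for counting error alone. The control library held 11785 barcodes with 69853026 unique molecular identifiers (UMIs), and the knockout library held 10615 barcodes with 42795121. A barcode carried a median of 5641 UMIs and 2074 genes in the control against 3745 UMIs and 1498 genes in the knockout, and the median mitochondrial share was 3.50% against 3.93%. After filtering, 10928 control and 10023 knockout cells remained.

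The targeted gene was looked at first. In NK-like cells, 11 Ptger3 UMIs were counted in the control library (0.176 counts per 1000000 UMIs, CPM, exact Poisson interval 0.0881 to 0.316) and 0 in the knockout library, where 3 counts would correspond to 0.0810 CPM. The control level was 2.18-fold that floor of the knockout library. Over all deposited barcodes it was 3.88-fold the floor, with 19 control UMIs, 11 of them in NK-like and 5 in dendritic-like cells, against 0. These folds leave out the counting error of the control. The interval of the log2 ratio in NK-like cells reached up to -0.58. At 1 depth of 2000 UMIs per cell, 0.0511% of control NK-like cells held a Ptger3 UMI (0.101% before thinning), while 0 of 8629 knockout cells did, which allows up to 0.0427% by the exact binomial interval. Dendritic-like cells of the control held the transcript in 5 of 183 cells (2.73%, median 4467 UMIs against 5813 in NK-like cells), and 0 of 177 did in the knockout (up to 2.06%), so the transcript was not found there in a type other than NK cells either. The NK-like share of the control lies below its dendritic-like share, and at so few counts free RNA is not separated from low expression in NK cells. Tags at the 3' end outside the deleted exon check nothing, and the deleted exon is not given. Ncr1, which drives Cre, stood at 797 CPM in the control and 820 in the knockout (log2 ratio of knockout over control 0.04). Among thinned NK-like cells 76.9% and 77.1% held an Ncr1 UMI, against 96.5% and 91.7% before thinning, and 51.9% and 37.9% of unthinned dendritic-like cells did, at medians of 4467 and 3281 UMIs.

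Clustering both libraries together gave NK-like cells as the main class, with 9882 control cells (90.4%, exact binomial interval 89.9 to 91.0) and 8805 knockout cells (87.8%, 87.2 to 88.5). The libraries parted almost completely: an NK-like cluster led by Gprin3 and Styk1 held 9345 control and 136 knockout cells, and another led by Styk1 and Klra3 held 106 and 8593. Such clusters can stand for a library and not a cell type. A smaller NK-like cluster led by Nr4a3, Ccl4 and Xcl1 held 431 control cells (3.94%) and 76 knockout cells (0.758%); several of its leading genes also differ between the libraries, so no difference in size is read from it. Macrophage-like cells, led by C1qa, C1qc and Vcam1, made up 1.62% of control cells (1.39 to 1.87) and 3.83% of knockout cells (3.46 to 4.23), although the sort was for NK cells. T cell-like clusters made up 1.27% against 2.37%, dendritic-like cells 1.67% against 1.77%, and ILC1-like cells, a related innate lymphoid type, 0.403% against 0.658%. With other cluster settings the T cell-like share in the control dropped to between 0.503% and 0.641%, and the order of the NK-like shares turned under the stricter cell filter (89.3% and 90.1%). Clusters led by interferon or cell division genes of NK cells were kept out of the NK-like class by a rule set after the data were seen. Together they held 1.89% of control and 1.07% of knockout cells (4.29% and 2.72% at a Leiden resolution of 1, 5.55% and 2.27% under the stricter filter). In the main clustering the interferon cluster was level between the libraries (0.842% and 0.848%). The gap lay in the division cluster, with 114 control cells (1.04%) and 22 knockout cells (0.219%). Platelet transcripts led a further cluster (1.43% and 1.48%), haemoglobin transcripts another (0.467% and 0.459%) and histone and division genes a mixed cluster (0.824% and 0.519%), and these stayed unnamed. In the macrophage-like cluster 71.1% of cells held a UMI of Ncr1, Klrb1c or Klrk1, so pairs of cells in 1 droplet, or free RNA, remain possible there. The doublet caller marked 1 barcode and is reported as not having worked.

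The comparison of NK-like cells addresses what loss of EP3 does to the adhesion and killing programmes of these cells, the subject named in the title of the series. A total of 62327905 control and 37028152 knockout UMIs covered 7331 measured genes. The median log2 ratio of knockout over control was -0.07 with an SD across genes of 0.45. Most of these cells come from the control-led cluster in the control library and from the knockout-led cluster in the knockout library. Ratios were therefore also taken within 4 clusters found after each gene was centred within its library, which held 4418, 2714, 2267 and 546 control cells and 4349, 2594, 1693 and 222 knockout cells.

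At the upper end, Wls, which carries Wnt proteins to the cell surface, stood at 51.0 CPM in the control and 569 in the knockout library, an 11.2-fold difference (log2 3.48, 3.43 to 3.53). Cirbp, a cold-inducible RNA-binding protein, was 5.07-fold higher (log2 2.34) and the galectin gene Lgals3 was 3.63-fold higher (log2 1.86). The mitochondrial protein gene Higd1a (1.41), the NK receptor genes Klrb1b (1.16) and Klrc1 (1.14), AY036118 (1.08), Ifitm10 (1.07), Paxx (1.04), the pro-apoptotic gene Bbc3 (1.02), Mir142hg (0.96), Ncf4 (0.89) and Fam204a (0.88) followed. At the lower end, the chaperone gene Hsph1 stood at 135 CPM in the control and 10.2 in the knockout library, a 13.3-fold difference (log2 -3.73, -3.88 to -3.58). Camk2n1 (-3.12), the co-chaperone genes Stip1 (-1.92), Dnajb4 (-1.73), Dnaja1 (-1.61) and Chordc1 (-1.51), the retroviral restriction gene Apobec3 (-1.85), Msl3 (-1.66), Sfpq (-1.51), Ptp4a3 (-1.42), Cep350 (-1.41), the immediate early gene Fosb (-1.38) and the cytoskeletal linker gene Macf1 (-1.32) were next. Each of these 26 genes had its direction in all 4 centred clusters. They were picked for their ratio over NK-like cells, and these clusters split NK-like cells of the same libraries, so this is no separate support. Of the 21 with at least 10 UMIs in macrophage-like, dendritic-like and T cell-like cells nearly free of NK transcripts, 20 had the same direction there, with Lgals3 as the exception, but the intervals of 10 of the 20 held 0. The 11 highest genes other than Wls and Cirbp summed to -0.02 (-0.16 to 0.12) in those cells, against 1.12 in NK-like cells. Outside the naming rule, chosen after their values were seen, the predicted genes Gm8797 (3.26), Gm26740 (-3.47) and Gm4070 (-1.80) lay equally far out.

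**Figure D1:**
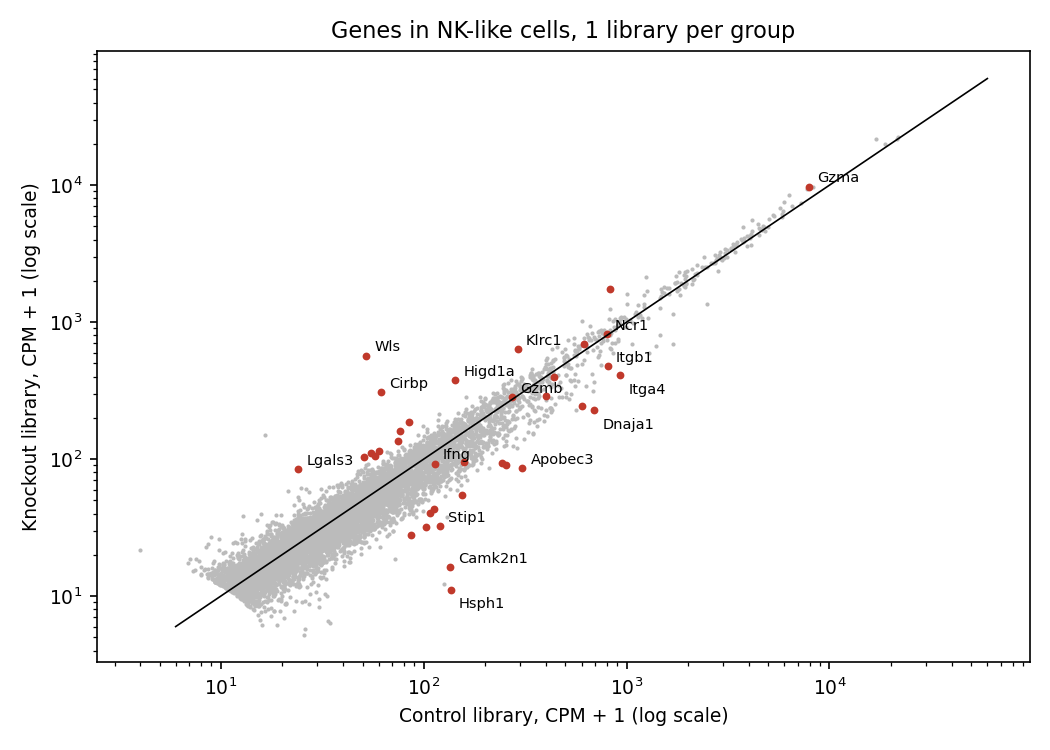
CPM plus 1 of each measured gene in NK-like cells of the control library (horizontal, log scale) and the knockout library (vertical, log scale), with grey points for 7331 genes, red points for the genes at both ends of the ranking and those fixed beforehand except Ptger3, and a line of equality. Wls (51.0 and 569 CPM) lies far above the line and Hsph1 (135 and 10.2) far below it.

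Of 31 measured genes for integrins and other adhesion molecules, 14 were lower by at least 0.32 on the log2 scale, the size that marks a gene as higher or lower throughout, 0 were higher by that size and 17 lay between. Their median log2 ratio was -0.16 (-0.19 to -0.14), at the 4.39th percentile of 10000 random lists matched on expression, inside their middle 95%, and it was below 0 in each of the 4 centred clusters. Itga4, the integrin alpha 4 chain that pairs with beta 1 or beta 7 and binds VCAM-1 and fibronectin (ENSMUSG00000027009, chromosome 2, 79255426 to 79333123 in the GRCm38 annotation), stood at 932 CPM in the control and 409 in the knockout library, 2.28-fold lower (log2 -1.19, -1.21 to -1.16). Its partner Itgb1 was 1.68-fold lower (log2 -0.75), and Crtam (-1.07), Itgax (-0.95), the integrin-linked cytoskeletal gene Tln1 (-0.90), Itgam (-0.73) and Itgal (-0.47) were also lower. Itgb2 (-0.16) stayed inside that bound. Long transcripts as a whole were lower in the knockout library. Genes in the shortest of 8 exon length classes had a median log2 ratio of 0.21 and those in the longest -0.44 (Spearman correlation -0.51 across 7326 genes, which are not independent replicates). The adhesion list had a median exon length of 4933 bases. In the class of 4639 to 5765 bases the lower quartile of all measured genes was -0.42, past the size that marks a gene. Counts of higher or lower members, here and below, were not set against the share over all measured genes, so they alone do not set a list apart. Length-adjusted values are log2 ratios minus the median of the 300 genes nearest in exon length. So adjusted, the list median was -0.24 and the ratio was -0.71 for Itga4, -0.70 for Itgb1 and -0.53 for Tln1. Crtam (-0.93), Itgax (-0.84) and Itgam (-0.60) also stayed past the bound, but Itgal (-0.24) came inside it. Ratios of single genes below are not adjusted unless stated. Some of those called lower come inside the bound once adjusted, such as Prkch (-0.29), Prkcq (-0.15) and Pfkp (-0.13). The summed list stood at -0.34 (-0.35 to -0.33) in NK-like cells and at -0.14 (-0.27 to -0.01) in the other cell types nearly free of NK transcripts.

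**Figure D2:**
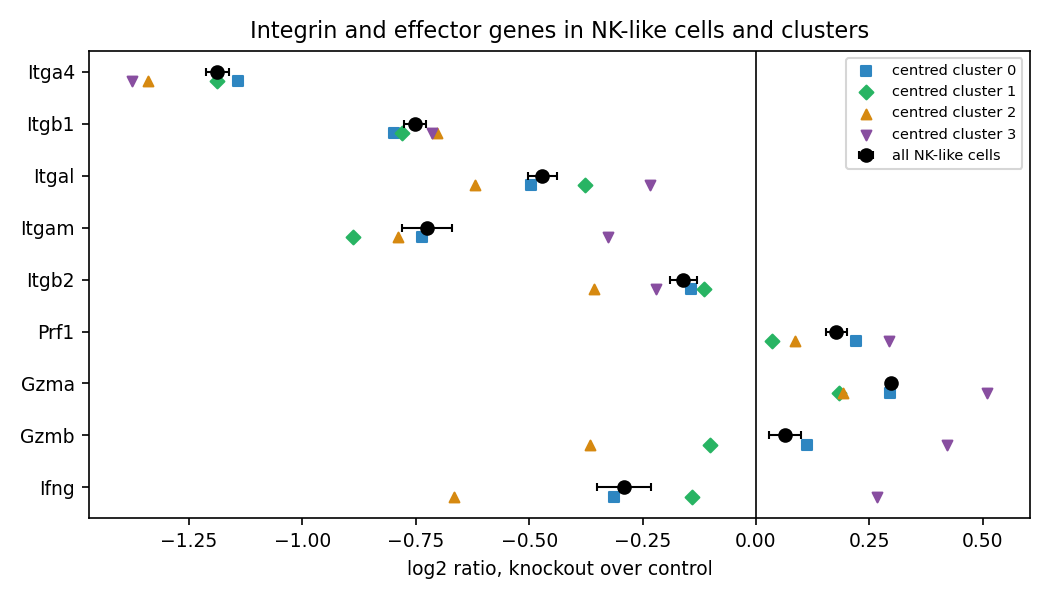
Log2 ratio of knockout over control (horizontal) for 9 integrin and effector genes (vertical) in NK-like cells, with black points and 95% counting intervals for all NK-like cells and coloured symbols for 4 centred clusters. Itga4 lies at -1.19 and on the left of 0 in every cluster, while Gzmb and Ifng lie on both sides.

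**Figure D3:**
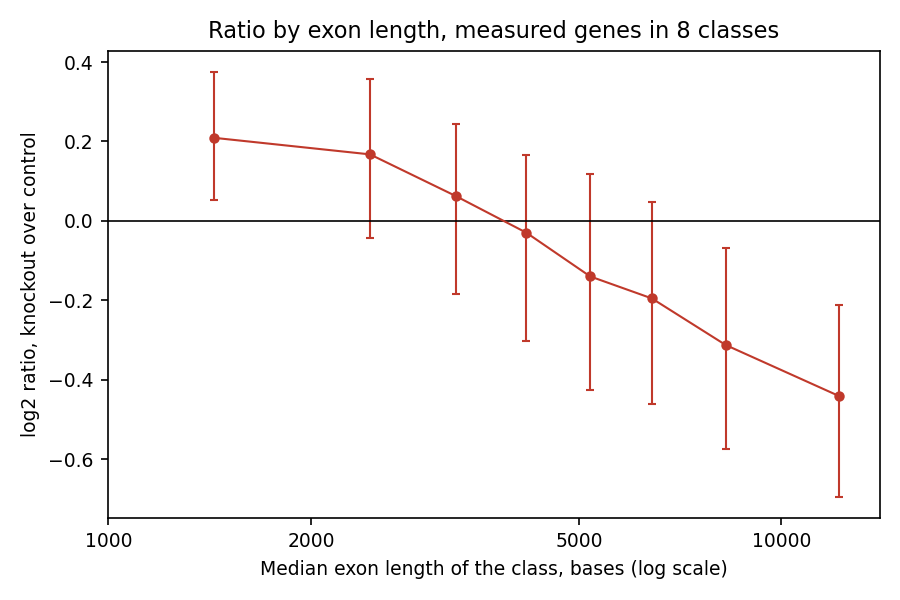
Median log2 ratio of knockout over control (vertical) in NK-like cells against the median exon length in bases (horizontal, log scale) of 8 classes of measured genes, with bars from the lower to the upper quartile of genes. The median goes from 0.21 in the shortest class to -0.44 in the longest.

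Killing genes differed little and in both directions. Of 21 measured cytotoxic effector genes, 2 were higher, 3 were lower and 16 lay between, and their median log2 ratio was 0.13 (0.10 to 0.15), at the 96.2nd percentile of random lists (length-adjusted 0.02). Gzma, the most abundant granzyme, stood at 7932 CPM in the control and 9756 in the knockout (log2 0.30), and the perforin gene Prf1 at 615 and 696 (0.18), both inside the bound. Gzmb (0.06) had no common direction over the centred clusters. The 2 higher genes were Gzmk (1.57, 7.69 CPM in the control and 22.8 in the knockout) and Stxbp2 (0.47), and the lower ones included Gzmm (-0.98) and Cst7 (-0.62). Among 9 measured cytokine and chemokine genes, with a median of -0.01 (length-adjusted 0.12), 3 were lower and 2 higher: the chemokines Ccl4 (-1.07), Xcl1 (-0.998) and Ccl3 (-0.68) were lower and Ltb (0.52) was higher, while Ifng (-0.29) lay inside the bound and changed sign between clusters. In the smallest cluster, which Ccl4, Xcl1 and Ccl3 help to lead, all 3 lay inside the bound (-0.13, -0.26 and 0.10).

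Receptor genes went both ways. Of 26 activating receptor and adaptor genes 7 were lower and 3 higher (median -0.12, 13.7th percentile), with Slamf7 (-0.99), Ly9 (-0.74) and Plcg2 (-0.64) lower and Slamf6 (0.64) higher. Of 14 measured inhibitory receptor genes 6 were lower, among them the phosphatase gene Ptpn6 (-1.11) and Klra7 (-0.47), and 5 were higher, among them Klrb1b and Klrc1. Their median of -0.22 (length-adjusted -0.05) turned to 0.35 in the few NK-like cells without UMIs of other lineages' markers. Chemokine receptor and trafficking genes (12 measured, median -0.02, length-adjusted -0.11) held 2 higher members, Cxcr3 (0.53) and S1pr4 (0.43), and 2 lower ones, among them Ptger4 (-0.61). Of 23 cytokine receptor and JAK-STAT genes 6 were lower and 1 higher (median -0.18, length-adjusted 0.02), and Il12rb2 (-0.87) and Stat4 (-0.82), parts of interleukin 12 signalling, were lower while Il7r (1.12) was higher.

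Of 14 genes that mark less mature NK cells 4 were higher and 5 lower, with a median of 0.17 at the 98.1st percentile of random lists (length-adjusted -0.05, 87.4th percentile of lists matched on length). Il7r, the protease inhibitor gene Ctla2a (0.69), Cxcr3 and Ltb were higher, and the growth factor receptor gene Kit (-1.56) and Xcl1 were lower. Of 13 genes that mark mature NK cells 5 were lower and 1 higher (median -0.25, but 0.04 in the smallest centred cluster), with Cd55 (-1.06), Zeb2 (-0.91), Itgam and Lgals1 (-0.56) lower. Of 28 NK transcription factor genes 10 were lower and 2 higher (median -0.21, 3.73rd percentile, length-adjusted -0.14, 30.1st percentile of lists matched on length). Klf6 (-0.91), Zeb2, Ikzf3 (-0.78) and Mxd4 (-0.75) were among the lower ones. Length-adjusted, Klf6 stood at -0.88, Ikzf3 at -0.43, Mxd4 at -0.41 and Zeb2 at -0.36. Markers of neighbouring cell types differed along with these groups. The T cell list had a median of 0.23 (length-adjusted 0.12) over 6 measured genes, with Cd3g (1.30) and Trbc1 (0.34) higher and Cd3d (0.25) and Trbc2 (0.20) inside the bound, and its summed level was 679 CPM in the control and 821 in the knockout. The ILC1 list summed to 64.0 CPM in the control and 122 in the knockout, and both measured members, Rora (1.67) and Il7r, were higher (median 1.39, but 0.64 in NK-like cells without other lineages' marker UMIs and 0.68 at a list minimum of 1 CPM).

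Of 19 prostanoid receptor and synthesis genes only Ptger4, the EP4 receptor gene, and Ptges3 (-0.51) reached the measuring minimum, and both were lower (median -0.56). Ptger4 turned to 0.10 in NK-like cells without other lineages' marker UMIs. Of 28 genes of cAMP and G protein signalling 9 were lower and 1 higher (median -0.16, 16.4th percentile, length-adjusted 0.05), with the G protein regulator Rgs1 (-1.18), the cAMP-responsive genes Nr4a2 (-1.40) and Nr4a1 (-0.82, but 0.06 in the smallest centred cluster) and Creb1 (-0.81) lower. Protein kinase C genes (9 measured, median -0.22, length-adjusted -0.06) held 2 lower members, Prkch (-0.59) and Prkcq (-0.43), 1 higher, Prkcz (0.41), and 6 between, such as Prkd3 (-0.25). Of 21 immediate early genes 9 were lower and 2 higher (median -0.20, 3.92nd percentile, length-adjusted -0.32), with Fosb, Fos (-1.14), Cd69 (-0.99) and Klf6 lower.

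Heat shock genes were the lowest list. Of 11 measured members 10 were lower in the knockout library and 0 higher, and the median of -1.13 (-1.15 to -1.11) lay below all 10000 random lists. Hsph1, Dnaja1, the mitochondrial chaperonin gene Hspd1 (-1.31) and Hsp90aa1 (-1.31) were the lowest. The summed list was also lower in macrophage-like, dendritic-like and T cell-like cells nearly free of NK transcripts (-0.86, -0.96 to -0.75, against -1.22 in NK-like cells). Interferon response genes were lower too: 14 of 21 were lower and 0 higher, with a median of -0.46 (-0.57 to -0.43) at the 0.155th percentile. Slfn8 (-0.88), Ifi203 (-0.81), Irf9 (-0.81) and Ifi209 (-0.77) were examples, while the median mitochondrial share differed as given above.

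Of 48 nuclear oxidative phosphorylation genes 6 were higher, 0 lower and 42 between (median 0.14, 99.85th percentile), led by Ndufa12 (0.62), Sdhd (0.43), Ndufa7 (0.40) and Ndufb4 (0.36). Most of these transcripts are short, and the length-adjusted median was 0.02. Glycolysis genes had a median of 0.07 (86.7th percentile, length-adjusted 0.04) with 4 of 14 higher, such as Slc2a1 (0.59) and Tpi1 (0.45), and 2 lower, Hk1 (-0.72, 0.09 in the smallest centred cluster) and Pfkp (-0.60). Of 37 genes of the actin cytoskeleton and motility 12 were lower and 1 higher (median -0.06, length-adjusted -0.14), with S100a6 (-1.12), Myh9 (-0.91), Dock2 (-0.83) and S100a4 (-0.73) lower. Antigen processing and MHC class I genes (15 measured, median 0.00, length-adjusted -0.11) held Nlrc5 (-0.88) and H2-Q7 (-0.33) as lower and H2-T23 (0.38) as higher, with H2-D1 (0.30) inside the bound. Apoptosis and survival genes (17 measured, median -0.02, length-adjusted 0.00) held 5 lower members, such as Bcl2a1b (-1.37) and Pim2 (-1.07), and 2 higher, Bbc3 and Birc3 (0.46); Bcl2a1b was -0.23 over all deposited barcodes.

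Mitochondrially encoded genes had a median of 0.09 (length-adjusted -0.08), with mt-Nd6 (-1.02) lower and mt-Atp6 (0.27), mt-Co2 (0.26) and mt-Nd3 (0.26) inside the bound. The ribosomal protein list had a median of 0.06 (length-adjusted -0.12) with 5 of 89 higher, such as Rpl13a (0.58), and 4 lower, such as Rpl29 (-0.86). As written, that list also takes 6 measured S6 kinase genes, among them Rps6ka3 (-0.52, 0.03 in the smallest centred cluster) and Rps6ka5 (-0.45), and without them the median was also 0.06.

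Proliferation genes (11 measured, median -0.03, length-adjusted -0.06) held Stmn1 (0.72) and Hmgb2 (0.34) as higher and Top2a (-0.62) and Rrm1 (-0.43) as lower. Counting NK-like cells and the interferon and division clusters, 59.2% of thinned control cells (58.2 to 60.2) and 68.7% of knockout cells (67.7 to 69.7) held at least 2 UMIs of this list, with 99 and 178 cells below the depth left out, and 94.2% and 91.0% did before thinning. Hmgb2 supplies most of those UMIs, and without Hmgb2, Stmn1 and Tubb5, left out after the data were seen, the shares were 11.1% and 10.2%. The division cluster of NK cells held 1.04% of control and 0.219% of knockout cells, and 1.04% and 0.249% after centring within each library. The mixed cluster of histone and division genes held 0.824% and 0.519%. These measures do not share a direction with the full list, and no difference in cycling is read from the list.

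Among NK-like cells, 206 of 9882 in the control and 383 of 8805 in the knockout held no UMI of other lineages' markers. B cell and plasma cell markers summed to 128 CPM in the control and 116 in the knockout, with Ighm (-0.43) as the measured member. Myeloid markers summed to 42.1 and 58.4, with Ms4a6c at -0.13, and erythroid and platelet markers to 203 and 211, with Car2 at 0.01. In the control, Car2 alone gave 185 of the 203 CPM and Ighm 112 of the 128. Trbc1 and Trbc2 gave 338 and 171 of the 679 CPM of T cell markers. Most of the level outside the myeloid list thus came from a few genes. Cells without such UMIs are therefore not shown to be purer NK cells. Of the sex-linked genes 4 were measured (median -0.37): Kdm5d (-0.48) and Ddx3y (-0.45) were lower, Eif2s3y (0.33) was higher and Uty (-0.29) lay inside the bound, and Y-linked transcripts were thus counted in both pools. Xist had 3 UMIs in the control and 10 in the knockout library.

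**Figure D4:**
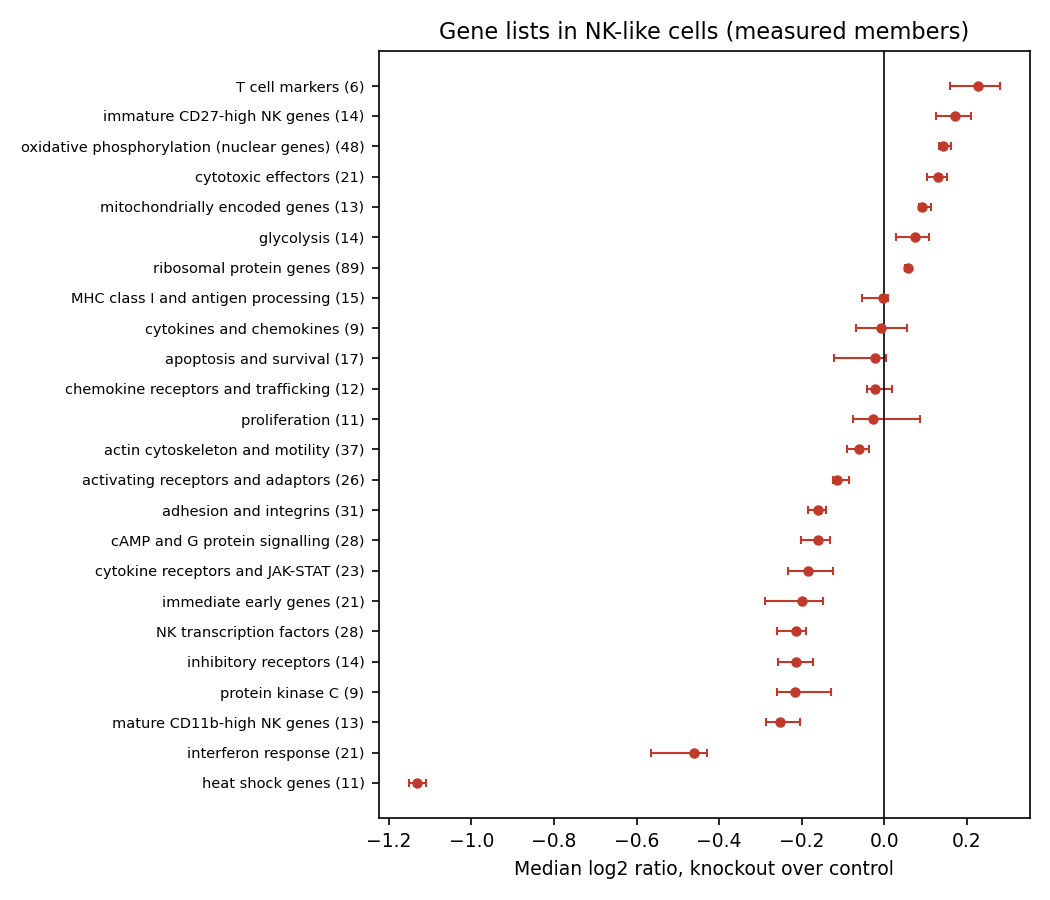
Median log2 ratio of knockout over control (horizontal) in NK-like cells for each gene list with at least 5 measured members (vertical, number of measured members in brackets), with bars for 95% intervals from counting error. The heat shock list lies farthest left at -1.13 and the interferon list next at -0.46, while the T cell list lies farthest right at 0.23.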

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

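The alternatives that add the interferon and division clusters, leave them out of the division share, remove the highest doublet scores or shorten the proliferation list were chosen after seeing the data, and the others before. No paired analysis was possible because each group is a single library. With no replicates no library could be left out, and depth limits the rest to counting intervals. The alternative of keeping doublets was not run, since none were removed, and ILC1-like, platelet or erythroid clusters did not appear under some cluster settings, which give no value there. Adding the interferon and division clusters, or removing the highest doublet scores, moved none of the 30 list medians out of its counting interval. Over all alternatives, 252 of 353 list medians and 986 of 1283 named gene ratios stayed within their intervals. The cytotoxic median ran from 0.088 to 0.18 and the adhesion median from -0.23 to -0.11, so neither changed sign. All 113 named genes past the size that marks a difference kept their direction under each alternative except in cells without other lineages' marker UMIs, where 109 did. In those cells Ptger4 reversed, and Cd3g, Trbc1 and Ighm have no ratio, since cells with their UMIs were left out. Rescaling shifts every ratio alike and thinning leaves each gene's share within a cell as it was on average, so these could hardly turn such a gene. Ptger3 values stayed within their intervals under the alternatives tried.

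Scaling by the median of ratios shifts every log2 ratio by 0.05 by construction and gave these list medians: cytotoxic 0.18, adhesion -0.11, trafficking 0.028, activating receptors -0.064, inhibitory receptors -0.16, immature NK 0.22, mature NK -0.20, transcription factors -0.16, cAMP signalling -0.11, immediate early -0.15, heat shock -1.08, interferon -0.41, glycolysis 0.12, oxidative phosphorylation 0.19, actin -0.0092, MHC class I 0.049, apoptosis 0.029, mitochondrial 0.14, ribosomal 0.11, erythroid 0.063. A total without mitochondrial and ribosomal protein genes, also 1 factor for every gene, gave cytotoxic 0.16, adhesion -0.12, activating receptors -0.080, transcription factors -0.18, cAMP signalling -0.13, heat shock -1.10, interferon -0.43, glycolysis 0.11, oxidative phosphorylation 0.18, actin -0.026, MHC class I 0.032, apoptosis 0.012, mitochondrial 0.13, ribosomal 0.092. Cells without other lineages' marker UMIs, only 206 control and 383 knockout cells by construction, gave cytotoxic 0.088, adhesion -0.23, trafficking 0.048, cytokines -0.25, activating receptors -0.13, inhibitory receptors 0.35, immature NK 0.11, mature NK -0.14, prostanoid -0.31, protein kinase C -0.45, immediate early -0.36, heat shock -1.41, glycolysis 0.0029, oxidative phosphorylation 0.21, MHC class I 0.073, apoptosis -0.19, mitochondrial 0.18, ILC1 0.64. In those cells the sex-linked list (0.20) and Ptger4 (0.10) reversed, a word kept for main values of at least 0.32 in size. The inhibitory receptor, trafficking and MHC class I medians also changed sign there, from smaller main values. With a minimum of 1 CPM, which adds rare genes, the B cell list reversed to 0.98. The myeloid (1.29) and cytokine (0.061) medians also changed sign, from main values below 0.32 in size. The others were inhibitory receptors -0.36, transcription factors -0.18, prostanoid -0.29, heat shock -1.21, apoptosis -0.13, erythroid 0.50, ILC1 0.68, sex-linked -0.29. A minimum of 50 CPM, which leaves out genes, gave trafficking 0.040, cytokines -0.15, activating receptors -0.21, inhibitory receptors -0.30, transcription factors -0.27, protein kinase C -0.34, immediate early -0.13, heat shock -1.21, interferon -0.57, proliferation 0.22, apoptosis 0.017, sex-linked -0.063.

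For the remaining settings the cause was not tested. Thinned cells gave adhesion -0.13, activating receptors -0.13, inhibitory receptors -0.27, heat shock -1.20, ribosomal 0.049, ILC1 1.31. The mean over centred clusters gave adhesion -0.21, prostanoid -0.49, heat shock -1.05, glycolysis 0.13, apoptosis 0.018, ribosomal 0.073, B cell -0.32. All deposited barcodes gave activating receptors -0.14, heat shock -1.09, proliferation -0.097, mitochondrial 0.083, T cell 0.37, B cell -0.35, myeloid 0.068, and Ncr1 at 775 against 777 CPM (control against knockout). The stricter cell filter gave immediate early -0.11, heat shock -1.10, mitochondrial 0.049, and equal weight per cell gave heat shock -1.20, ribosomal 0.047.

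Shares of cells are given as control against knockout, and their cause was not tested either. Leiden resolution 1 gave NK-like 88.9 against 86.9%, interferon and division 4.29 against 2.72%, T cell-like 0.641 against 2.05%. Resolution 0.3 gave NK-like 88.6% (knockout), dendritic-like 2.09% (knockout), T cell-like 0.577 against 1.71%. Centring within each library gave NK-like 91.0% (control), dendritic-like 2.18% (knockout), T cell-like 0.604 against 1.73%. The stricter filter gave NK-like 89.3 against 90.1%, interferon and division 5.55 against 2.27%, macrophage-like 1.31 against 2.79%, dendritic-like 1.10 against 1.15%, T cell-like 0.503 against 0.945%, ILC1-like 1.04% (knockout). Thinning before clustering gave NK-like 95.5 against 92.5%, interferon and division 1.38% (knockout), macrophage-like 1.03 against 2.86%, dendritic-like 0.976 against 1.51%, T cell-like 0.582 against 1.73%. Removal of the highest doublet scores gave NK-like 87.9 against 87.1%, interferon and division 2.99 against 1.38%, T cell-like 0.613 against 1.70%. The share with proliferation UMIs was 34.1 against 44.6% at a minimum of 3 UMIs, 94.2 against 91.0% in unthinned cells, where the order turned with the deeper control, and 11.1 against 10.2% without Hmgb2, Stmn1 and Tubb5. The share with an Ncr1 UMI was 96.5 against 91.7% in unthinned cells.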

Other observations

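The tests on other cell types, on lists matched for length and on gene position were chosen after the result was seen, as was the bound for heat shock genes in thinned cells. Cells of other types were the measure for several of them, and they fell into classes of unequal size: 31 control and 123 knockout macrophage-like cells, 56 and 83 dendritic-like cells, and 10 and 46 T cell-like cells.

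Gene lists were also set against random lists matched on length and expression. Heat shock genes lay below all of these, and interferon response genes lay low both with this matching (0.015th percentile) and without it (0.155th). Immediate early genes (0.08th, 3.92nd without matching on length), mature NK genes (1.26th, 6.98th), activating receptor genes (2.44th, 13.7th) and inhibitory receptor genes (0.05th, 6.74th) lay outside the middle 95% with this matching alone. The inhibitory list held 5 higher and 6 lower members, and its median was -0.22 before and -0.05 after the trend with length was removed. Oxidative phosphorylation genes (78.75th, 99.85th without matching on length) and immature NK genes (87.4th, 98.1st) came inside the middle 95%. Cytotoxic effector genes (80.7th, 96.2nd) and NK transcription factor genes (30.1st, 3.73rd) lay inside it both ways. Over 2506 genes with at least 30 UMIs in the other cell types, the correlation of the log2 ratio with exon length was -0.52 in NK-like cells and -0.20 in the other cells. The other cells held far fewer UMIs, and counting error in their ratios weakens such a correlation. Whether the trend itself is weaker there can therefore not be told.

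Heat shock genes were lower in the knockout library in NK-like cells (median log2 ratio -1.13). A change that arises only inside NK cells is argued against by the other cell types, where the summed list stood at -0.86 (-0.96 to -0.75) and was lower in macrophage-like (-0.62), dendritic-like (-0.98) and T cell-like cells (-1.03), while free NK RNA cannot supply it, since the list stood at 112% and 144% of its NK-like level there. The earlier selections of other cells gave -0.77 and -0.82. Thinned cells (median -1.20) decide nothing about fewer UMIs per cell, since random thinning leaves each gene's share within a cell as it was on average. Thinning also weighs cells alike, and equal weight per cell without thinning gave -1.20 too. A difference between the libraries that reaches every cell type, such as handling before capture, may account for it, since the ratio in other cells was 69.9% of that in NK-like cells on the log2 scale; an effect of NK genotype on neighbouring cells, or between the pooled mice, stays open because each group is 1 library.

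Itga4 was among 14 of 31 adhesion genes that were lower in the knockout library. The trend with transcript length was -0.48 at the length of Itga4, which stood at -0.71 (-0.74 to -0.69) after its removal. That interval is for counting error and does not measure how genes of like length scatter about the trend. In the longest of 8 length classes the quartiles were -0.69 and -0.21, and Itga4 at -1.19 lay below them. As this scatter was not part of the test, the trend is not decided as the whole cause for Itga4. For the adhesion list it cannot be told apart: the median lay at the 18.0th percentile of lists matched on length, but it was already inside the middle range (4.39th percentile) without that matching, and after the trend was removed 22 of 31 members stayed below 0 and the median was -0.24, against -0.16 before. A change inside NK cells may lower Itga4 but cannot be told apart from a wider difference, since its ratio in the other cells was -0.39 (-0.99 to 0.24) and the classes did not agree, with T cell-like at -1.83 (-2.79 to -0.84), dendritic-like at 0.74 (-0.13 to 1.69) and macrophage-like at 0.84 (-2.01 to 6.29, 1 against 9 UMIs), the last 2 holding 0. The list test was first read as pointing to length, before its place without that matching was noticed, and the Itga4 test as pointing to NK cells, before the values per class were seen. Itgb1 (-0.86) and Tln1 (-1.22) were lower in the pooled other cells too. They were not split by class, and the make-up by class differs between the libraries, so a lower level cannot be told apart from that.

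Among the genes at both ends of the ranking, a change inside NK cells alone is argued against for the summed 13 lowest genes (-1.64, -1.89 to -1.39, in the other cells), for the 8 of them that are not chaperone genes (-1.44, -1.80 to -1.08), and for Wls and Cirbp (2.53, 1.36 to 4.01), with each class on the same side, although for Wls and Cirbp the macrophage-like (2.57, -0.01 to 7.93, 1 control UMI) and T cell-like intervals (0.88, -0.84 to 3.26, 3 control UMIs) held 0. Of the lowest genes, Camk2n1 and Dnajb4 had at most 1 UMI per library there, and Ptp4a3 (-0.31, -1.38 to 0.85) and Macf1 (-0.23, -1.05 to 0.65) had intervals that hold 0, so nothing is decided for these singly. For the other 11 highest genes it cannot be told apart: they summed to -0.021 (-0.16 to 0.12) in the other cells, but AY036118 and Lgals3 gave 411 and 128 of their 591 control UMIs, so little is known of the rest. The split was made after the sum of all 13, now 0.05 (-0.09 to 0.18), had been seen, and AY036118 entered later, when the naming was corrected to the written rule. Of the 26 genes, 2, Wls and Dnajb4, lie within 10 Mb of Ptger3, whose floxed allele both groups carry. Within 10 Mb of Ncr1, which carries Cre in the knockout group alone, lie 0. The windows were chosen after the result was seen. Genes outside them are by definition not linked within them, so the count tests nothing about longer linked stretches. Bbc3 (from 16308393) and Fosb (from 19302696) lie on chromosome 7, as does Ncr1 (from 4337724). The bound set for linkage, 13 of the 26 genes, could hardly be met, so the count decides nothing for Wls and Dnajb4. Wls, the highest gene, starts 2.19 Mb beyond Ptger3.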
